A study of Mus musculus with 4 samples.

How the data were processed

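The tables used hold counts per gene and cell that the authors deposited: per the file headers and names, replicate 1 is in reads per cell and replicate 2 in molecules per cell, both after error correction of the molecular barcodes. Per the file headers, the counts came from the BD WTA Multiplex Rhapsody Analysis Pipeline, version 1.8 for replicate 1 and 1.9.1 for replicate 2, with GRCm38, PhiX and GENCODE M19 as references. Per the submitters' processing notes, mm10/GRCm38.p6 was the build, with HISAT2 2.0.5 and Bowtie2 named as aligners. Per the labels' protocols, the cells were sorted lamina propria ILC3 of the small intestine, marked with mouse sample tags, pooled, and captured on a BD Rhapsody cartridge. The antibodies of the sort were not given in the sources used here. Raw reads were not used here.

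Each replicate is a tag library and a whole transcriptome library of the same cells. Cells were taken by the deposited tag calls. The sample characteristics give tag 4 for replicate 1, but the deposited tag list gives tag 8 and 0 cells were called tag 4, so tag 8 was used. Replicate 2 is tag 12 in every source. Cells of 7 other tag values (4 in replicate 1 and 3 in replicate 2) were not used, nor were cells the authors' pipeline called multiplets (815 of 18635 in the run of replicate 1, or 4.37%, and 1997 of 19173 in that of replicate 2, or 10.4%) or undetermined (1450 and 239). Doublets within a tag are not removed by those calls. Scrublet marked 2 of 5054 cells (0.0396%) in replicate 1, where it has not worked, and 30 of 4989 (0.601%) in replicate 2, so leaving out the cells with the highest 5% of Scrublet scores (253 and 249 cells) was added as an alternative.

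The tables held 21792 and 20841 genes, 19380 of them in both. Cells with at least 300 detected genes and under 20% mitochondrial counts were kept. Each replicate was clustered on its own in scanpy 1.11.5: counts scaled to 10000 per cell and log-transformed, 2000 highly variable genes less the members of the tested lists (1910 and 1875 left), values capped at 10, 30 principal components, 15 neighbours, Leiden resolution 1.0, seed 0. Clusters were named from 13 marker lists: LTi-like ILC3, NCR-like ILC3, all ILC3, ILC1 or NK, ILC2, T, B or plasma, myeloid, epithelial, stromal or endothelial, mast, erythroid and cycling cells. The thresholds for a name were set after the clusters had been seen. Each name needed at least 3 markers of its list in 5% of cells or more. Names other than T-cell-like and ILC3-like needed a mean log2 ratio of detection shares of at least 1.0 over the other clusters (offset 0.02). Other cell types also needed a marker among the 10 leading genes, without which such a cluster stayed unnamed. T-cell-like clusters were named next, on a mean share of 35% or more for the CD3 chains and whatever their T-cell ratio, which ran from -0.46 to 1.91. NCR-like or ILC1 or NK followed. Remaining clusters in which a fixed ILC3 marker was found more often than in the other cells were ILC3-like, and were split into LTi-like and other ILC3-like at 0.5 of the highest mean share of LTi markers. Leading genes were those with the largest ratio among genes found in at least 20% of a cluster.

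Counts were summed per replicate and class (at least 20 cells each), and the 3 ILC3-like classes were fitted together in edgeR 4.0.16 with TMM factors, filterByExpr (minimum count 10, minimum total 15), the replicate as a block, and the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. Of 10092 genes that passed the filter, 8558 that were not clustering features in either replicate were tested, with 2 residual degrees of freedom and a biological coefficient of variation of 0.160. CPM are over the TMM-scaled total of the genes that passed the filter, whereas values per 10000 are over all counts of a class. P-values measure only the spread between these samples, which may be technical, because nothing in the labels says that the replicates came from separate animals. Classes were built from the expression of the same cells, so a test describes the classes and is not independent of their definition. Camera with a preset correlation of 0.01 was run over 16 lists for NCR-like against LTi-like cells (and, without being fixed beforehand, for the other comparisons), with an estimated correlation beside it and fry, which tests whether genes move on balance one way. The lists were cytokines and growth factors, MHC class II presentation, cytotoxicity and NK receptors, immediate early genes, heat shock proteins, interferon-stimulated genes, homing and tissue retention, lymphoid transcription factors, cytokine receptors, glycolysis, oxidative phosphorylation, CXXC1 and H3K4 methyltransferase complexes, cell survival and death, clock genes, neuropeptide, lipid and metabolite sensing, and ribosomal proteins.

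Shares of cells carry Wilson 95% intervals, which, like the floors given for a count of 0, cover counting error only. A gene with 0 counts in a class was given as N-fold in each replicate, against a floor of 3 counts per replicate and relative to all counts of the class. Several reads can come from a single molecule, so this value is not a lower bound in replicate 1, which is in reads. Cells of replicate 2 were also thinned to 1500 molecules each for the levels. Symbols were matched to GENCODE release M21 on GRCm38 for coordinates (8529 of the 8558 tested genes, 99.7%), a release that need not be the authors' own.

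The groups, the comparisons, the tests, the marker and gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named, per comparison, Cxxc1, Il7r, Il22, Il17a, Ccr6, Ncr1 and Cd4 always, and 1 gene whose values are not shown. It added up to 3 called members with the smallest p per tested list that holds a called gene. It added the 8 genes with the largest fitted change in each direction among called genes with above-median abundance and the same sign in both replicates. Genes of the lists mentioned beyond that rule were chosen after the values had been seen, from those called.

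Alternatives were DESeq2 size factors, the DESeq2 Wald test, no filter on low counts, no replicate block, clustering features tested too, Leiden resolutions 0.6 and 1.5, 1000 highly variable genes, a stricter cell filter (at least 600 genes and under 10% mitochondrial counts), Scrublet doublets left out, a detection gate (Ccr6 without Ncr1, Ncr1 without Ccr6, neither), numbers of cells with a count in place of counts, and each replicate alone. Chosen after the data had been seen were the classes without a heat-shock-led cluster, without cells that have a CD3 or Trac count, without cells that have a Lyz2, Csf1r, C1qa, C1qb or Cd14 count, and without the highest Scrublet scores.

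The tests were checked on simulated data with the same depths and, for each gene, the spread that the fit gave on average at its abundance. Of genes changed 4-fold, 71.2% were recovered for NCR-like against LTi-like cells, 81.8% for other ILC3-like against LTi-like cells and 86.2% for other ILC3-like against NCR-like cells. At 2-fold the shares were 38.5%, 34.3% and 44.6%, and at 1.5-fold 4.48%, 6.15% and 15.4%. Of unchanged genes, 2 of 8247, 1 of 8254 and 2 of 8241 were called. A moved list was recovered each time, with 0 of the other lists called. Genes were drawn independently of each other, and the classes were given. The simulation therefore cannot check list tests on correlated genes, nor classes built from the same cells. Nor can it check genes whose own spread is wider than that average, so the few calls among unchanged genes may be optimistic. In the data, the estimated correlation was 0.55 for ribosomal proteins and 0.52 for heat shock proteins in NCR-like against LTi-like cells. Software was R 4.3.3, limma 3.58.1, DESeq2 1.42.0, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.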

Results

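Group 3 innate lymphoid cells (ILC3) live in the gut wall and secrete interleukin-22, which protects the epithelium. The series title concerns Cxxc1, which encodes a CpG-binding subunit of H3K4 methyltransferase complexes, in intestinal ILC3 during ageing. The single-cell data described here are of control ILC3 from young C57BL/6 mice, so they show which cells were captured, how their classes differ, and at what level Cxxc1 is expressed, with no group to compare it against. There were 2 replicates. Replicate 1 held 5302 cells of its tag with a median of 4650 reads and 1036 genes per cell, and replicate 2 held 5010 cells with a median of 2366 molecules and 1223 genes. The share of non-zero values equal to 1 was 26.8% in replicate 1 and 66.3% in replicate 2, so the values of the replicates are in different units and are not compared with each other directly. After filtering, 5054 and 4989 cells remained.

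The LTi-like, other ILC3-like and NCR-like classes, called ILC3-like here, made up 38.8% (Wilson 95% interval 37.5 to 40.2) of replicate 1 and 65.3% (64.0 to 66.6) of replicate 2. The NCR-like class was named without a requirement for ILC3 markers. Lymphoid-tissue-inducer-like (LTi-like) cells, named for markers such as Ccr6, Cd4 and Cd81, were 17.1% and 46.3% of all cells. NCR-like cells, led in both replicates by Xcl1, Klrb1c, Klrd1 and Ncr1, were 5.80% and 4.19%. A class that was neither, led in both by Gjb2, Chad and Car2, genes of a gap junction, a matrix protein and a carbonic anhydrase, was 16.0% and 14.8%. T-cell-like cells, with T-cell receptor transcripts, were 49.6% (48.2 to 50.9) of replicate 1 and 26.2% (25.0 to 27.5) of replicate 2, although the labels describe sorted ILC3.

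Smaller classes expressed markers of stroma or endothelium such as Col1a1 and Dcn (6.94% and 1.24%), of cycling cells such as Mki67 (1.17% and 2.45%), of ILC2 such as Gata3 and Calca (1.19% and 1.503%), and of B or plasma cells such as Jchain (0.732% and 0.722%). Mast-cell-like cells with Mcpt2 and Cpa3 were 0.910% of replicate 1 and formed no cluster in replicate 2. Myeloid-like cells with Ccl22 and Lyz2 were 1.12% of replicate 2 and took no name in replicate 1. No cluster was named epithelial, erythroid, or ILC1 or NK. An unnamed cluster of 27 cells in replicate 2 had epithelial cells as its best match (mean log2 ratio 2.14). It was led by Tff2, Gkn3 and Muc6, and no epithelial marker was among its leading genes. An unnamed cluster of 9 cells in replicate 1 was led by Ccl21a, Aqp1 and Mmrn1. The T-cell-like class of replicate 2 includes 47 cells led by Klra7 and Klra5, whose best match was ILC1 or NK but whose mean share for the CD3 chains was 0.674. In all, 0.673% and 1.44% of cells stayed unnamed. Among ILC3-like cells alone, LTi-like cells were 43.9% (41.8 to 46.1) and 70.9% (69.3 to 72.4), other ILC3-like cells 41.1% (39.0 to 43.3) and 22.7% (21.3 to 24.2), and NCR-like cells 14.9% (13.4 to 16.6) and 6.41% (5.62 to 7.31). Clustering choices moved the shares beyond these intervals, which cover counting only: of all cells in replicate 1, other ILC3-like cells were 8.37% with 1000 variable genes and NCR-like cells 10.9% at Leiden 1.5. LTi-like cells fell below other ILC3-like cells there at Leiden 1.5 (12.1% against 15.4%) and without the highest Scrublet scores (14.8% against 18.3%). With the detection gate they did so in both replicates (3.80% against 31.1%, and 16.6% against 45.7%). The gate counts ILC3-like cells with neither Ccr6 nor Ncr1 detected as other ILC3-like. LTi-like cells were a single cluster in replicate 1, led by Vegfa and Cd83, and 5 clusters in replicate 2, of which one was led by the heat shock genes Hspa1b and Hspa1a.

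**Figure D1:**
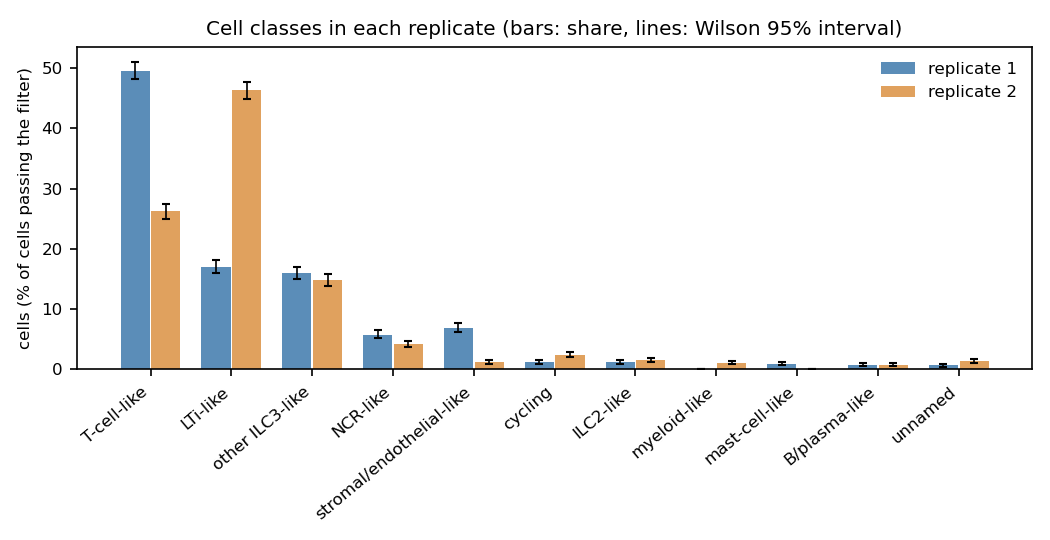
Share of cells passing the filter, in percent, per named class and replicate, with Wilson 95% intervals as lines. T-cell-like cells were the largest class of replicate 1 (49.6%) and LTi-like cells the largest of replicate 2 (46.3%).

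In replicate 1, T-cell receptor transcripts were more frequent in the NCR-like class than in LTi-like, other ILC3-like and stromal or endothelial cells. A count of Cd3d, Cd3e, Cd3g or Trac was present in 53.9% (48.2 to 59.5) of NCR-like cells in replicate 1 and 10.5% (7.05 to 15.4) in replicate 2, against 10.6% (8.68 to 12.8) and 6.06% (5.16 to 7.11) of LTi-like cells, 13.1% (10.98 to 15.6) and 9.88% (7.93 to 12.2) of other ILC3-like cells, and 94.0% and 98.3% of T-cell-like cells. Stromal or endothelial cells, which should lack them, had one in 16.8% (13.3 to 21.1) and 16.1% (9.004 to 27.2) at a higher depth. The NCR-like share of replicate 2 and the shares of LTi-like and other ILC3-like cells were no higher than in stromal or endothelial cells. In replicate 1, however, B/plasma-like and mast-cell-like cells had one in 56.8% (40.9 to 71.3) and 67.4% (53.0 to 79.1). Their median depth was lower than that of NCR-like cells, so the stromal share may understate the background there. The NCR-like class also expressed genes of ILC1 and NK cells such as Gzma, Itga1 and Klre1. Its mean log2 ratio of detection shares was -0.43 and -0.67 for the ILC3 markers. For the ILC1 or NK markers it was 1.39 and 1.00, and for the NCR-like markers 1.77 and 1.95. These values do not show that the class is made up of NCR-positive ILC3. It is counted as ILC3-like here by its name only, and its comparisons may set ILC1 or NK cells against ILC3.

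Cxxc1 is a protein-coding gene on the plus strand of chromosome 18, from 74216124 to 74221496 in GRCm38 coordinates. A Cxxc1 count was present in 15.3% (13.1 to 17.9) of LTi-like, 15.7% (13.4 to 18.4) of other ILC3-like and 22.5% (18.1 to 27.6) of NCR-like cells in replicate 1, and in 16.6% (15.2 to 18.2), 16.9% (14.4 to 19.8) and 13.4% (9.43 to 18.7) in replicate 2. Relative to all counts, Cxxc1 stood at 0.799, 0.833 and 0.958 per 10000 in replicate 1 and at 0.775, 0.817 and 0.978 in replicate 2. T-cell-like cells had Cxxc1 at 1.11 and 1.01 per 10000 and stromal or endothelial cells at 0.730 and 0.726. Median counts per cell, which set how often a gene is detected, were 4506.5, 5316 and 5234 in the 3 ILC3-like classes of replicate 1 and 2583, 2279 and 1818 in replicate 2.

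Il22, on chromosome 10 from 118204942 to 118210047, was the most widely detected of the ILC3 cytokines. An Il22 count was present in 83.2% (80.5 to 85.5) of LTi-like, 79.9% (77.0 to 82.5) of other ILC3-like and 21.5% (17.2 to 26.6) of NCR-like cells in replicate 1, and in 75.5% (73.7 to 77.3), 85.5% (82.8 to 87.9) and 24.4% (19.1 to 30.7) in replicate 2. Stromal or endothelial cells, which should lack Il22, had a count of it in 14.8% (median 10211 counts per cell) in replicate 1 and 30.6% (median 5028) in replicate 2. T-cell-like cells, of which some kinds can make Il22, had one in 12.9% (median 4359) and 13.4% (median 1988.5). The NCR-like share of Il22 lay above the stromal share in replicate 1 and below it in replicate 2. With cells of replicate 2 thinned to 1500 molecules it was 24.2% (18.2 to 31.5) against 15.3% (8.24 to 26.5), intervals that overlap. Per 10000 molecules of those thinned cells, Il22 was lower in NCR-like than in stromal or endothelial cells, at 5.56 against 9.49. Thinned B/plasma-like and myeloid-like cells had Il22 in 36.1% and 26.9%, and T-cell-like and ILC2-like cells in 11.2% and 10.3%. Il22 in NCR-like cells of replicate 2 was thus not shown to lie above background. Igkc, an immunoglobulin chain that ILC3 should lack, had a count in 19.4%, 18.7% and 28.0% of LTi-like, other ILC3-like and NCR-like cells in replicate 1 and in 38.0%, 33.8% and 31.6% in replicate 2.

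Other cytokines were confined to fewer cells. Il17a, which encodes a neutrophil-recruiting cytokine, had a count in 7.31% of LTi-like, 7.68% of other ILC3-like and 3.75% of NCR-like cells in replicate 1, and in 16.6%, 16.1% and 0.478% (1 of 209) in replicate 2, against 10.7% and 4.20% of T-cell-like cells and 0.855% and 0 of 62 stromal or endothelial cells. Il17f was found in 22.3% and 43.8% of LTi-like, 13.9% and 26.4% of other ILC3-like and 2.39% and 0.957% of NCR-like cells, against 1.42% and 11.3% of stromal or endothelial cells, and is one of the LTi markers used for naming. Csf2, which encodes the myeloid growth factor GM-CSF, was found in 13.0% and 21.2% of LTi-like, 20.4% and 27.3% of other ILC3-like and 3.41% and 13.9% of NCR-like cells, against 2.83% and 2.37% of T-cell-like and 1.14% and 8.06% of stromal or endothelial cells. Ifng, which encodes the macrophage-activating cytokine interferon-gamma, ran the other way: 1.62% and 0.606% of LTi-like, 5.82% and 2.30% of other ILC3-like, 18.4% and 12.9% of NCR-like and 17.8% and 28.0% of T-cell-like cells, with 3.13% and 1.61% of stromal or endothelial cells.

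**Figure D2:**
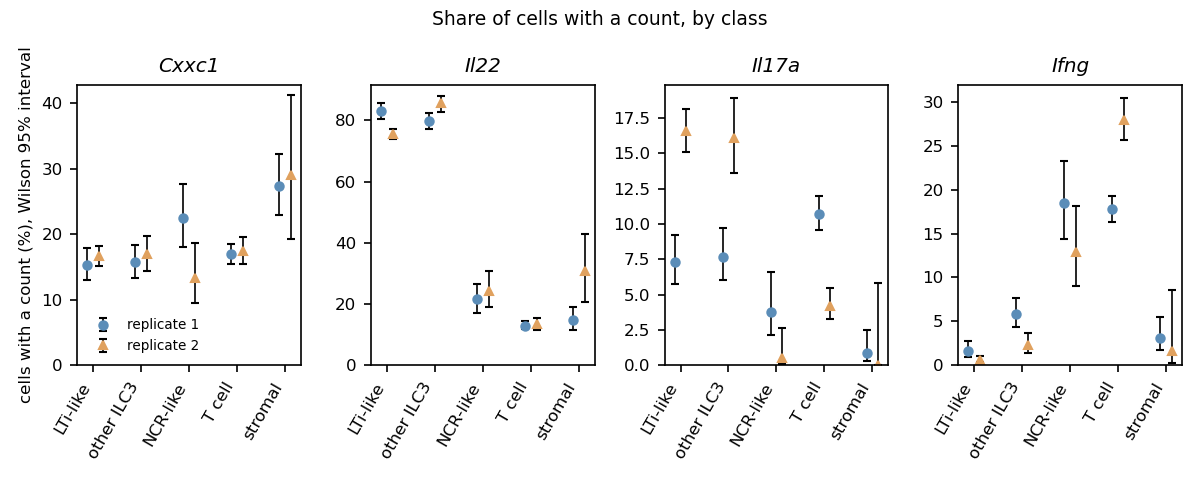
Percent of cells with a count of Cxxc1, Il22, Il17a and Ifng in LTi-like, other ILC3-like, NCR-like, T-cell-like and stromal or endothelial cells, with Wilson 95% intervals. Circles are replicate 1 and triangles replicate 2. Il22 was found in 83.2% and 75.5% of LTi-like cells, Cxxc1 in 15.3% and 16.6%.

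Ncr1 and Cd4 took part in the clustering and were not tested. Ncr1, a natural cytotoxicity receptor, was found in 24.9% and 42.1% of NCR-like, 14.3% and 6.09% of other ILC3-like and 1.28% and 0.823% of LTi-like cells, against 0.160% and 0.0765% of T-cell-like cells and 0.855% and 0 of 62 stromal or endothelial cells. Cd4 was found in 13.0% and 36.2% of LTi-like, 4.21% and 6.36% of other ILC3-like, and 14.0% and 1.91% of NCR-like cells, against 29.6% and 60.02% of T-cell-like cells and 5.13% and 17.7% of stromal or endothelial cells. Tbx21, the regulator of type 1 programmes and a marker used for naming, was found in 32.8% and 29.7% of NCR-like, 9.91% and 3.92% of other ILC3-like, and 2.09% and 1.60% of LTi-like cells, against 1.42% and 0 of 62 stromal or endothelial cells. Eomes, which NK cells need, was found in 6.83% of NCR-like cells (and 0.855% of stromal or endothelial cells) in replicate 1 and 0 of 209 in replicate 2, where the Wilson interval reaches 1.805% at a median of 1818 molecules per cell.

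NCR-like cells had less Il22, Tnfsf11 and Hbegf and more of the cytotoxicity genes than LTi-like cells. The genes for the secreted factors IL-22, RANKL and HB-EGF were lower in NCR-like cells: Il22 at a log2 fold change of -3.31 (SE 0.24, 2 replicates), Tnfsf11 (-3.16, SE 0.21) and Hbegf (-3.45, SE 0.25). Il22 is also a naming marker of ILC3. Il22 stood at 7738 and 5618 CPM in LTi-like cells and at 724 and 620 in NCR-like cells. The granule and killing genes Ctsw (5.09, SE 0.23), Nkg7 (6.15, SE 0.37), Gzmb (4.75, SE 0.30) and Fasl (6.85, SE 0.41) were higher in NCR-like cells, as was Klrd1 (6.53, SE 0.35), a subunit of inhibitory and activating NK receptors. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 4.9e-06 for Il22, 3.4e-06 for Tnfsf11, 4.9e-06 for Hbegf, 2.6e-07 for Ctsw, 1.9e-06 for Nkg7, 2.8e-06 for Gzmb, 1.9e-06 for Fasl and 1.0e-06 for Klrd1. Of 8558 tested genes, 406 were higher and 600 lower in NCR-like cells, 1006 in all, of which 990 were not naming markers. The same sign in both replicates, held by 1005 of them, largely follows from the call. Over all tested genes the sign was the same in 63.6%, and the replicates' log2 fold changes had a Pearson correlation of 0.46. Without the replicate block the count was 215, with classes drawn by Ccr6 and Ncr1 detection 453, and with DESeq2 637.

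**Figure D3:**
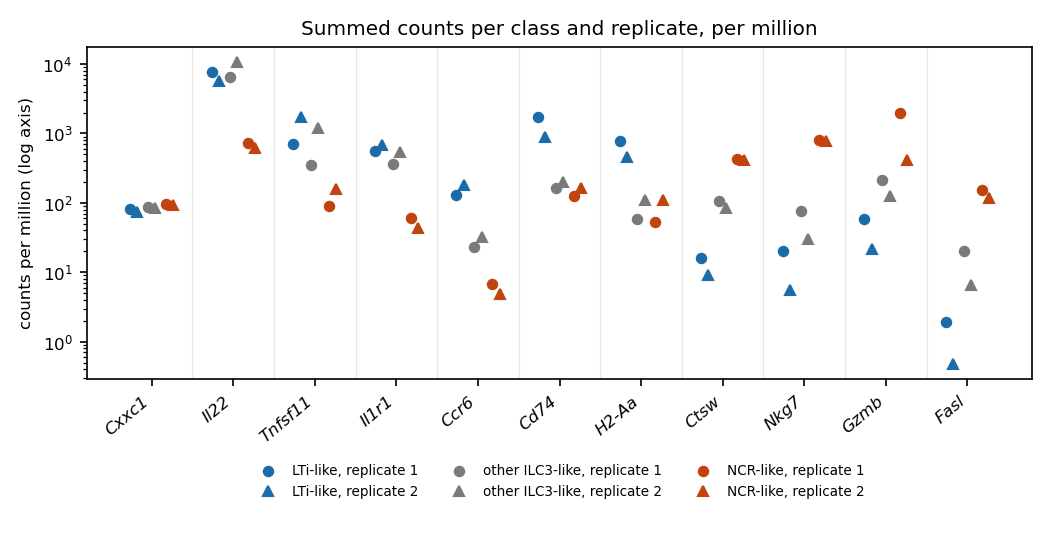
Summed counts per class of 11 genes, as CPM on a log axis. Circles are replicate 1 and triangles replicate 2, with blue for LTi-like, grey for other ILC3-like and orange for NCR-like cells. Cxxc1 lay at 82.7 and 74.7 in LTi-like and 94.8 and 94.4 in NCR-like cells, whereas Gzmb lay at 59.1 and 21.7 and at 1984 and 414.

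Cxxc1 did not pass the test between these classes, at a log2 fold change of 0.26 (SE 0.19, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.437). Its list, CXXC1 and H3K4 methyltransferase complexes, held 1 gene that was higher among 21 tested, Setd1b, a catalytic partner of CXXC1 (0.73, SE 0.20, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.0351), and 0 adjusted over the list alone. Its median log2 fold change was 0.06, and camera gave an adjusted p of 0.224 (adjusted p = 0.441 with an estimated correlation). Fry gave an adjusted p of 0.106 for change one way and of 0.0059 for change in either direction. For either direction fry also gave an adjusted p of 0.0089 for oxidative phosphorylation, a list with 0 genes called adjusted over the list alone. Il7r, the receptor for the survival cytokine IL-7 and a naming marker of ILC3, did not pass (-0.40, SE 0.25, with -1.09 in replicate 1 and 0.26 in replicate 2; edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.338).

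Of 17 tested cytokines and growth factors, 8 were lower in NCR-like cells, among them Il22, Tnfsf11, Hbegf and Il17a, and 3 higher (Ifng, Il16 and Tnfsf10), with 6 that did not pass. Il17a fell by 2.75 (SE 0.52) with unequal replicates, -1.81 and -6.73, and only 1 count in NCR-like cells of replicate 2. Adjusted over the list alone, 9 were lower and 4 higher. The list's median was -1.14 (-0.70 and -2.30 in the replicates), and camera called it lower (adjusted p = 2.66e-06, and adjusted p = 0.265 with an estimated correlation). The cytotoxicity and NK receptor list had 18 of 20 members higher and 0 lower, from Cd226 at 1.62 to Klrc2 at 6.96, with Gzma, a naming marker of ILC1 or NK cells, at 4.87 (SE 0.37) and Klrc1, the inhibitory receptor NKG2A, at 5.32 (SE 0.65). Klrk1 and Prf1 of this list are naming markers too. The NCR-like class was named for NK-receptor genes, so a higher list was in part fixed in advance. Adjusted over the list alone all 20 were higher, the median was 4.52, and camera gave an adjusted p of 1.1e-74 (adjusted p = 0.265 with an estimated correlation). As given above, CD3 or Trac counts were also more frequent in the NCR-like class of replicate 1, at 53.9% of cells.

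Genes of antigen presentation to CD4 T cells were lower in NCR-like cells. Cd74, the invariant chain, fell by 3.21 (SE 0.29), and H2-Aa (-3.11, SE 0.38) and H2-Ab1 (-2.93, SE 0.49) were lower too, with adjusted p of 2.4e-05, 0.000219 and 0.00211 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The replicates were unequal, with -3.86 and -2.03 for H2-Aa and -4.19 and -1.35 for H2-Ab1. Cd74 stood at 1714 and 892 CPM in LTi-like cells and at 125 and 162 in NCR-like cells. Of 10 tested MHC class II genes, 7 were lower and 0 higher, also 7 and 0 adjusted over the list alone, with a median of -2.52 (-3.02 and -1.43 in the replicates). Camera called the list lower (adjusted p = 4.32e-08, and adjusted p = 0.408 with an estimated correlation).

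Receptors for cytokines that steer these cells also differed. Il1r1, whose ligands induce IL-22, was lower (-3.44, SE 0.23), whereas Il12rb2, which completes the IL-12 receptor, was higher by 5.58 (SE 0.48) and Il21r by 4.16 (SE 0.28), at adjusted p of 3.4e-06, 1.5e-05 and 3.4e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Il1r1 and Il23r are naming markers of ILC3. Of 27 tested cytokine receptors, 8 were higher, including Tnfrsf9 and Il18rap, and 4 lower, including Il23r and Il2ra, with 9 and 7 adjusted over the list alone. The median was 0.50 although each replicate alone gave -0.04 and 0.14, and camera gave an adjusted p of 0.0873 (adjusted p = 0.441 with an estimated correlation). Among 30 lymphoid transcription factors and associated genes, 6 were lower, including Tox2 (-3.00, SE 0.37), Tcf7 and the list's one enzyme, Arg1, which breaks down arginine (-3.85, SE 0.32). The 5 higher were Ikzf2, Ikzf3, Zbtb16, Satb1 and Lef1, genes that T cells also express, and 2 of the list were higher with cells that have a CD3 or Trac count left out. Adjusted over the list alone the counts were 5 higher and 8 lower. The list's median was 0.02, its mean -0.17 and its camera direction down, with an adjusted p of 0.219 (adjusted p = 0.645 with an estimated correlation).

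Adhesion and homing genes moved in both directions. Itga1, a collagen-binding integrin chain and a naming marker of ILC1, was higher in NCR-like cells by 3.90 (SE 0.29), and Itgae, whose product binds epithelial E-cadherin, by 4.97 (SE 0.51), with 5.30 in replicate 1 and 2.31 in replicate 2, where it had 3 counts. Cd69, a tissue-retention receptor, was lower (-0.96, SE 0.15). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 5.2e-06, 6.4e-05 and 0.00119. Of 18 homing and retention genes, 7 were higher, including Cxcr3 and Ccr9, and 3 lower, including Gpr183, with 8 and 3 adjusted over the list alone. The median was 0.38, and camera gave an adjusted p of 0.00386 (adjusted p = 0.408 with an estimated correlation).

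Activation and stress genes were called lower in NCR-like cells more often than higher. The AP-1 family genes Jun (-1.93, SE 0.15) and Atf3 (-2.09, SE 0.16) fell, as did Zfp36 (-1.60, SE 0.16), whose product destabilises cytokine mRNA, at adjusted p of 8.6e-06, 6.5e-06 and 4.5e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 24 immediate early genes, 11 were lower, including Fos and Egr1, and 3 higher (Dusp2, Myc and Nr4a2), with 12 and 4 adjusted over the list alone. Jun and Zfp36 were not called when cells with a count replaced counts. The median was -0.37, and camera gave an adjusted p of 0.00111 (adjusted p = 0.441 with an estimated correlation). Of 12 heat shock genes, 8 were lower and 0 higher, or 9 and 0 adjusted over the list alone, led by Hspa1a (-2.78, SE 0.56, with -1.33 and -3.80 in the replicates), Hspa1b (-2.53, SE 0.52) and Hsp90aa1 (-1.002, SE 0.21). Their median was -0.59, and camera gave an adjusted p of 0.000427 (adjusted p = 0.441 with an estimated correlation, and 0.096 without the replicate block).

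Of 17 glycolysis genes, 3 were lower in NCR-like cells and 0 higher: Pfkfb3, which raises glycolytic flux (-2.74, SE 0.25), the hexokinase Hk2 (-1.42, SE 0.23) and Pkm (-0.65, SE 0.16). Adjusted over the list alone 5 were lower and 1 higher. The median was -0.41, and camera gave an adjusted p of 0.0207 (adjusted p = 0.441 with an estimated correlation, and 0.096 without the replicate block). Of 45 oxidative phosphorylation genes only Ndufs5, a subunit of complex I, was lower (-0.79, SE 0.19), and 0 were called adjusted over the list alone, with a median of -0.03 and a camera adjusted p of 0.848 (adjusted p = 0.895 with an estimated correlation). Of 50 ribosomal protein genes 12 were higher, by 0.49 to 0.69, including Rpl12, Rpl38 and Rpl39, and 0 lower. Adjusted over the list alone 30 were higher, the median was 0.42, and camera gave an adjusted p of 4.32e-08 (adjusted p = 0.441 with an estimated correlation). With cells that have a CD3 or Trac count left out, 3 ribosomal protein genes were higher and 2 adjusted over the list alone, and without the replicate block 0 and 0.

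Interferon-stimulated genes split: of 22, Ifi27l2a (2.92, SE 0.28) and Ifitm2 (3.27, SE 0.34), which restricts virus entry, were higher and 3 lower, including the GTPase Iigp1 (-1.73, SE 0.21) and Bst2, with the same counts adjusted over the list alone. The median was 0.18 (0.29 and -0.03 in the replicates), and camera gave an adjusted p of 0.307 (adjusted p = 0.660 with an estimated correlation). Of 23 survival and death genes, 4 were higher, including the pro-death Bcl2l11 (2.01, SE 0.23) and the anti-death Bcl2a1d (2.21, SE 0.26), and 2 lower, Gadd45b and the cell-cycle inhibitor Cdkn1a (-1.18, SE 0.16), or 7 and 3 adjusted over the list alone. Their median was 0.07, but -0.07 and -0.15 in the replicates, and the mean was 0.30, with a camera adjusted p of 0.109 (adjusted p = 0.441 with an estimated correlation). Of 12 clock genes only Nr1d1, a nuclear receptor that represses transcription in the clock, was lower (-2.24, SE 0.25), also adjusted over the list alone, with a median of -0.34 and a camera adjusted p of 0.211 (adjusted p = 0.441 with an estimated correlation).

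Receptors for neuropeptides, lipids and metabolites moved both ways, with 4 of 21 higher and 6 lower, or 6 and 9 adjusted over the list alone. Adora2a, a receptor for adenosine, was higher by 3.30 (SE 0.29), and Ffar2, which senses short-chain fatty acids, was lower (-1.74, SE 0.20). Ramp1, a subunit of the receptor for the neuropeptide CGRP, was lower (-3.39, SE 0.48) and had 0 counts in NCR-like cells of replicate 2. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 1.8e-05, 0.000137 and 0.000689. The median was -0.49, and camera gave an adjusted p of 0.286 (adjusted p = 0.469 with an estimated correlation). Of the 16 lists, camera called 8, of which 0 held with an estimated correlation, and fry called 3: cytokines and growth factors, cytotoxicity and NK receptors, and homing.

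**Figure D4:**
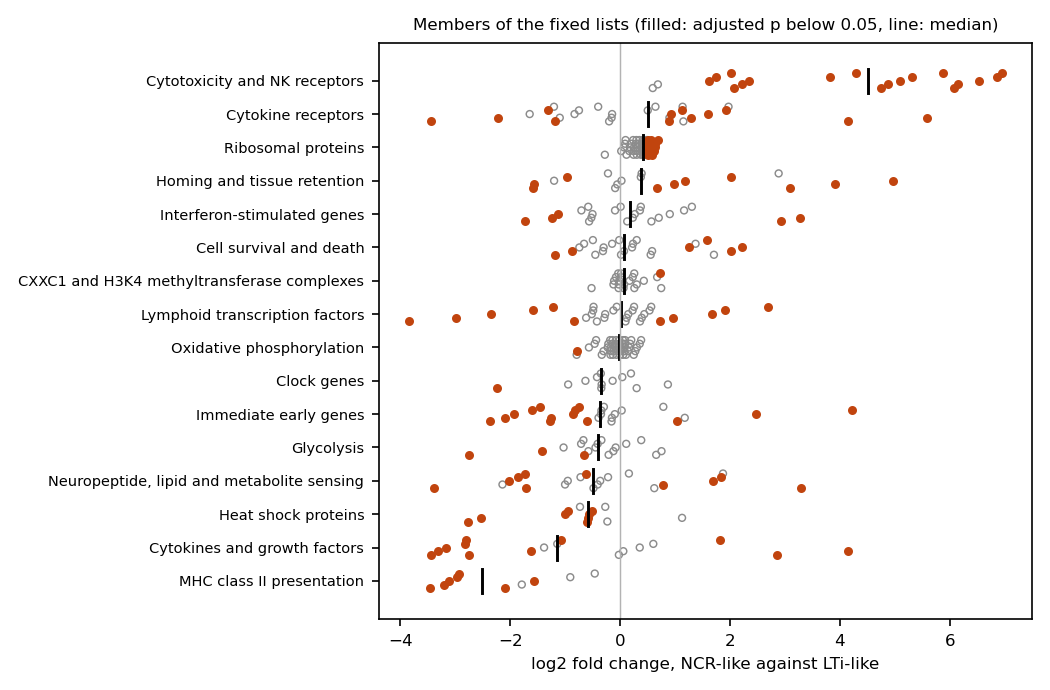
Log2 fold change of NCR-like against LTi-like cells for each tested member of the 16 lists, filled where the adjusted p was below 0.05, with a line at each median. Medians ran from 4.52 for cytotoxicity and NK receptors to -2.52 for MHC class II presentation.

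Among the genes with the largest changes, several were almost absent from NCR-like cells. Shtn1, which encodes a cytoskeletal protein of growing axons, had 146 and 366 counts in LTi-like cells and 0 in NCR-like cells of both replicates. In replicate 2 this is at least 8.00-fold lower. In replicate 1 a floor of 3 reads gives 20.3-fold, which is not a lower bound because several reads can come from a single molecule. Arhgef28, a guanine nucleotide exchange factor, had 332 and 279 counts against 3 and 0. The chemokine receptor Ccr6 (-4.48, SE 0.30) and the tetraspanin Cd81 (-5.07, SE 0.40), both naming markers, were lower. So were the RNA-binding gene Khdrbs3 (-4.45, SE 0.56), Tifa (-4.25, SE 0.51), the ADP receptor P2ry1 (-4.22, SE 0.56) and the RNA-editing enzyme Apobec1 (-4.21, SE 0.36). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 4.5e-05 for Shtn1, 3.1e-05 for Arhgef28, 3.4e-06 for Ccr6 and 1.6e-05 for Apobec1. Of 54 genes named by rule and called between NCR-like and LTi-like cells, 37 stayed called under every alternative that kept the replicate block. Those that did not were Il17a, Jun, Zfp36, Hspa1a, Hspa1b, Hsp90aa1, Itgae, Cd69, Hk2, Pkm, Ndufs5, Setd1b, Ramp1, Rpl12, Rpl38, Rpl39 and Tifa.

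Other ILC3-like cells had less Ccr6, Cd74 and H2-Aa and more Ctsw and Gzmb than LTi-like cells, while Il22 and Il17a were not called. Il22 (0.36, SE 0.22, with -0.25 and 0.92 in the replicates), Il17a (0.41, SE 0.38), Il7r (0.01, SE 0.24) and Cxxc1 (0.12, SE 0.17) did not pass between these classes, at adjusted p of 0.770, 0.860, 0.994 and 0.921 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Ccr6, a naming marker, was lower (-2.49, SE 0.20), Cd74 (-2.81, SE 0.27) and H2-Aa (-2.97, SE 0.34), whereas Ctsw, a protease of killer cells, was higher by 2.97 (SE 0.22), Gzmb by 2.18 (SE 0.28) and Ifng by 2.69 (SE 0.39), each over 2 replicates. Cd74 stood at 1714 and 892 CPM in LTi-like and 165 and 201 in other ILC3-like cells, and Ctsw at 16.1 and 9.20 against 107 and 85.6. The adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.000135 for Ccr6, 0.000559 for Cd74, 0.0023 for H2-Aa, 9.5e-05 for Ctsw, 0.00506 for Gzmb and 0.0105 for Ifng. Of 8558 genes, 22 were higher and 23 lower in other ILC3-like cells, 45 in all, of which 40 were not naming markers. Each of the 45 had the same sign in both replicates, which largely follows from the call. Over all tested genes the sign was the same in 57.9%, at a Pearson correlation of 0.30. Without the replicate block 0 genes were called in edgeR, with 223 at unadjusted p below 0.05, whereas DESeq2 with the block called 44. Counting cells in place of counts gave 141 and the detection gate 23. Of 25 genes named by rule and called, only Ccr6, Cd74, Ctsw, Serpinb9 and Itga1 stayed called under every alternative that kept the block.

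Of 10 MHC class II genes, 5 were lower in other ILC3-like cells and 0 higher, including H2-Eb1 (-3.48, SE 0.51) and H2-DMb1 (-3.87), with a median of -2.90, and 9 were lower adjusted over the list alone. Of 20 cytotoxicity genes, 7 were higher and 0 lower, with a median of 1.48, or 14 adjusted over the list alone, including Nkg7 (2.15, SE 0.35), Fasl (3.56, SE 0.47), Gzmc (1.65) and Serpinb9, an inhibitor of granzyme B (1.64, SE 0.21). Neither list held with an estimated correlation or by fry: for MHC class II and for cytotoxicity alike, camera gave an adjusted p = 0.349 with an estimated correlation and fry an adjusted p of 0.434, in tests not fixed beforehand for this comparison. Of 17 cytokines, Ifng was higher and Lta, which encodes lymphotoxin alpha, lower (-1.05, SE 0.20), or 2 and 4 adjusted over the list alone. Of 18 homing genes, Itga1 (2.39, SE 0.28) and the gut-homing receptor Ccr9 (3.05, SE 0.49) were higher, or 4 higher and 2 lower adjusted over the list alone. Ccr9 stood at 46.0 and 5.55 CPM in LTi-like and 248 and 115 in other ILC3-like cells.

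Single members passed in further lists. The transcription factor Ikzf3 (1.88, SE 0.31), the costimulatory receptor Tnfrsf18 (1.00, SE 0.19), the survival gene Bcl2a1d (1.36, SE 0.25) and the lysophospholipid receptor Gpr34 (1.63, SE 0.31) were higher in other ILC3-like cells. The immediate early gene Egr1 (-1.61, SE 0.23), the chaperone Hsph1 (-1.25, SE 0.24), the survival gene Bcl2 (-0.85, SE 0.15), Ramp1 (-2.29, SE 0.35), the tetraspanin and naming marker Cd81 (-2.33, SE 0.25) and the nucleosome-binding gene Hmgn3 (-1.93, SE 0.33) were lower. Csf2rb, the shared receptor chain for IL-3, IL-5 and GM-CSF, was lower (-3.87, SE 0.69) at few counts, 121 and 16 in LTi-like against 7 and 1 in other ILC3-like cells. Its change turned positive with the detection gate (1.75) and without the highest Scrublet scores (0.0097). Csf2rb was also a leading gene of the Ccl22-led clusters of both replicates. Adjusted over the list alone, 10 of 12 heat shock genes were lower with a median of -0.57 (6 with a median of -0.44 without the heat-shock-led cluster, and 0 without the replicate block), 5 transcription factors were higher and 3 lower, 4 cytokine receptors higher and 1 lower, 5 sensing receptors higher and 2 lower, 1 survival gene higher and 2 lower, 0 immediate early genes higher and 2 lower, and 1 interferon-stimulated gene higher and 2 lower. No glycolysis, oxidative phosphorylation, H3K4 complex, clock or ribosomal protein gene was called in either way.

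Against NCR-like cells, other ILC3-like cells had more Il22, Tnfsf11 and Hbegf and less Klrd1 and Nkg7. Il22, a naming marker of ILC3, was higher by 3.67 (SE 0.24), Il17a by 3.16 (SE 0.52), Tnfsf11 by 2.40 (SE 0.21), Hbegf by 3.00 (SE 0.25) and Ccr6, a naming marker, by 1.99 (SE 0.35). Il17a rose by 2.02 in replicate 1 and by 7.29 in replicate 2, where NCR-like cells held 1 count. Klrd1 (-5.08, SE 0.33), Klre1 (-5.92, SE 0.46), which pairs with other lectin-like NK receptors, and Nkg7 (-3.99, SE 0.33) were lower, each over 2 replicates. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 1.2e-05 for Il22, 0.00324 for Il17a, 4.3e-05 for Tnfsf11, 0.00498 for Ccr6 and 1.2e-05 for Klrd1. Cxxc1 (-0.14, SE 0.20) and Il7r (0.41, SE 0.24) did not pass, at 0.746 and 0.357 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p. Of 8558 genes, 431 were higher and 168 lower in other ILC3-like cells, 599 in all, of which 586 were not naming markers. Each of the 599 had the same sign in both replicates, which largely follows from the call. Over all tested genes the sign was the same in 62.0%, at a Pearson correlation of 0.36. Without the replicate block the count was 73, with the detection gate 125 and with DESeq2 399. Of 43 genes named by rule and called, 18 stayed called under every alternative that kept the block, among them Il22, Tnfsf11, Hbegf, Klrd1 and Nkg7. Il17a was not called with DESeq2, Klre1 not with the gate, and Ccr6 not in 4 such alternatives.

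Of 17 cytokines, 8 were higher in other ILC3-like cells, among them Csf2 (1.61), Vegfa (1.76) and Tnf (1.11), and 2 lower, Ifng (-1.45) and the death ligand Tnfsf10 (-2.20), with a median of 1.11, or 10 and 3 adjusted over the list alone. Of 20 cytotoxicity genes, 13 were lower and 0 higher, with a median of -2.93, or 15 adjusted over the list alone, including the chemokines Ccl4 (-4.40, SE 0.53) and Ccl3 (-3.47, SE 0.48) and the receptor Klrc1 (-3.84, SE 0.62). The naming of the NCR-like class by NK-receptor genes in part fixed this in advance. In list tests not fixed beforehand for this comparison, camera gave an adjusted p = 0.257 with an estimated correlation for cytokines and for cytotoxicity alike, and fry an adjusted p of 0.0363 and 0.12. Of 27 cytokine receptors, 4 were higher, including Il1r1 (2.97, SE 0.23), Il23r (2.08, SE 0.23) and Il2ra (1.09), and 5 lower, including Il21r (-3.88, SE 0.28) and Il12rb2 (-3.74, SE 0.44), or 5 and 10 adjusted over the list alone.

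Of 24 immediate early genes, 8 were higher in other ILC3-like cells, including Jun (1.71, SE 0.15) and Atf3 (1.68, SE 0.16), and 2 lower, Myc (-1.69) and the phosphatase Dusp2 (-3.43, SE 0.42), or 15 and 4 adjusted over the list alone. Of 17 glycolysis genes, Pfkfb3 (2.67, SE 0.26), Hk2 (1.71, SE 0.23), Pkm (0.69, SE 0.17) and Pfkp (1.15) were higher and 0 lower, the same adjusted over the list alone. Of 30 transcription factors and associated genes, 6 were higher, including Arg1 (3.31, SE 0.32), Nfil3 (1.42, SE 0.20) and Runx3 (0.70), and Satb1 was lower (-1.20), or 8 and 3 adjusted over the list alone. Of 18 homing genes, Gpr183 (1.62, SE 0.24), an oxysterol receptor, and Cd69 (1.03, SE 0.15) were higher and 4 lower, including Itgae (-3.29, SE 0.45) and Itga1 (-1.52), or 4 and 8 adjusted over the list alone.

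Of 22 interferon-stimulated genes, Iigp1 (1.06, SE 0.21) and Rsad2 (1.48) were higher and Ifitm2 (-3.05, SE 0.36) and Ifi27l2a (-2.33, SE 0.30) lower in other ILC3-like cells, the same adjusted over the list alone. Of 23 survival genes, Cdkn1a (0.84, SE 0.16) and Gadd45b (0.77, SE 0.16) were higher and 4 lower, including Bcl2l11 (-1.68, SE 0.23), or 3 and 6 adjusted over the list alone. Nr1d1 was higher (2.09, SE 0.25) among 12 clock genes, or 2 adjusted over the list alone. Of 21 sensing receptors, 6 were higher, including Vdr, the vitamin D receptor (3.02, SE 0.41), and Ffar2 (1.60, SE 0.20), and 2 lower, Adora2a (-2.63, SE 0.29) and Ptger4 (-0.99), or 7 and 3 adjusted over the list alone. MHC class II, heat shock, oxidative phosphorylation, H3K4 complex and ribosomal protein lists held 0 called genes, and adjusted over the list alone 1 MHC class II gene was higher and 1 lower.

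Several of the genes with the largest increase in other ILC3-like over NCR-like cells were nearly missing from NCR-like cells. Shtn1 had 137 and 89 counts against 0 and 0, and Arhgef28 112 and 38 against 3 and 0. For Shtn1 this is at least 6.91-fold higher in replicate 2. The 18.2-fold of replicate 1, against a floor of 3 reads, is not a lower bound. Tifa (3.75, SE 0.53), P2ry1 (3.67, SE 0.59), Fam83a (3.66, SE 0.34), the lysosomal protease Ctsh (3.47, SE 0.51) and Khdrbs3 (3.43, SE 0.62) were higher by similar amounts. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.000135 for Shtn1, 0.000946 for Arhgef28, 0.00112 for Tifa and 0.00154 for Ctsh.

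The coordinates of other key genes are also those of GRCm38. Ccr6 is on chromosome 17 from 8236043 to 8257141, Cd74 on chromosome 18 from 60803848 to 60812652, Gzmb on chromosome 14 from 56258838 to 56262260, Il17a on chromosome 1 from 20730905 to 20734496, Ncr1 on chromosome 7 from 4337724 to 4345164 and Shtn1 on chromosome 19 from 58973356 to 59076100.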

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

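The tests of macrophages or dendritic cells counted among LTi-like cells and of deeper LTi-like cells, and the look at Cst3, were chosen only after the result was seen, and the values of Il17a below were picked out after the clusters had been seen.

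Il17a was far more frequent in a cluster of gamma-delta T-cell-like cells than in the other T-cell-like clusters. The cluster was led in both replicates by Trdc, Cd163l1, Blk and Trdv4. An Il17a count was present in 38.7% of its 563 cells in replicate 1 (Wilson 95% interval 34.8 to 42.8) and in 19.4% of its 139 cells in replicate 2 (13.7 to 26.8), against 0.855% and 0 of 62 stromal or endothelial cells. It drew attention because it was detected at this level in cells outside the comparisons made, in a sort of ILC3. Il17a was not a clustering feature, but it was among the leading genes of the cluster in replicate 1. Leading genes are picked for a high ratio after clustering, so that value is not independent of the pick. In other T-cell-like clusters Il17a had a count in 0.898% (the largest such cluster of replicate 1), 9.92% (a Tnfsf8-led cluster of replicate 1) and 2.97% of cells (the largest such cluster of replicate 2).

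Cytotoxicity and NK receptor genes were higher in NCR-like than in LTi-like cells, which T cells mixed into the class or free RNA of cytotoxic cells could produce. With cells that have a CD3 or Trac count left out, the median log2 fold change of the list was 4.53, against 4.52 with all cells, which argues against T cells with such a count. The summed list stood 16.5 times as high per 10000 counts in NCR-like cells as in stromal or endothelial cells in replicate 2, and 27.2 times in replicate 1. This argues against free RNA at the stromal level. Other classes stood higher than stromal cells (3.05) in replicate 1: mast-cell-like cells at 26.2 and B/plasma-like cells at 15.9, against 82.9 in NCR-like cells. In replicate 2 myeloid-like cells stood at 21.3, against 83.7 in NCR-like cells. A share of free RNA above the stromal level is therefore left open.

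MHC class II genes were higher in LTi-like than in other ILC3-like cells, which RNA of dendritic cells or macrophages could produce. The excess of myeloid markers was at most 0.369 of what the Cd74 difference would need (0.252 in replicate 2), above the bound of 0.25 set beforehand for ruling this out in full, and for Cst3, looked at afterwards, the ratio was 0.0191 and 0.0148. With cells that have a myeloid marker count left out, the list's median was -2.69, against -2.90, and 48.3% and 62.8% of those LTi-like cells still had an MHC class II count, against 15.8% and 30.2% of other ILC3-like cells. Depth differed by a ratio of median counts of 1.13 at most (0.848 in replicate 1). The cells left out were those with a Lyz2, Csf1r, C1qa, C1qb or Cd14 count, so dendritic cells without one stayed in, and that test does not cover them. The values argue against RNA of the Ccl22-led clusters, cells with such a count, and depth, each as the whole of the difference.

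Heat shock genes were higher in LTi-like than in NCR-like cells, which the heat-shock-led cluster of replicate 2 could produce on its own. Without the 648 cells of that cluster the median of the list was -0.43, against -0.59. Replicate 1 had no such cluster, and its own median was -0.43, against -1.07 in replicate 2 with the cluster. The cluster therefore cannot account for the difference in replicate 1. Whether a difference remains in replicate 2 without it cannot be told from the joint fit, which replicate 1 enters unchanged. No biological explanation was tested, because the design has 1 group.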

How the results depend on the processing

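Leaving out the heat-shock-led cluster, the cells with a CD3 or Trac count, the cells with a myeloid marker count and the highest Scrublet scores were tests chosen only after the result was seen. Of 45 counts of called genes under other settings, 28 stayed within 1.5-fold, 9 were higher and 8 lower. For NCR-like against LTi-like cells (1006), no replicate block gave 215 genes, the detection gate 453 (361 shared, 360 with the same sign) and DESeq2 637. For other ILC3-like against LTi-like cells (45), no filter on low counts gave 203, no replicate block 0, Leiden 1.5 114, 1000 variable genes 74, Scrublet doublets left out 99, the gate 23 (78.3% higher against 48.9%), cells with a count 141, no CD3 or Trac cells 69 and no high Scrublet scores 83. For other ILC3-like against NCR-like cells (599), no filter gave 963, no block 73 (83.6% higher against 72.0%), the gate 125, no high Scrublet scores 914 and DESeq2 399. Of the genes named and called, 31 of 54, 0 of 25 and 11 of 43 stayed called under every setting, and 37, 5 and 18 where the replicate block was kept, the 5 being Ccr6, Cd74, Ctsw, Serpinb9 and Itga1. Values near 0 changed sign. For NCR-like against LTi-like cells Cxxc1 was -0.27 with the gate and -0.00097 without CD3 or Trac cells. For other ILC3-like against LTi-like cells Cxxc1 was -0.20 at Leiden 1.5, -0.16 with 1000 variable genes, -0.25 with the gate and -0.069 without high Scrublet scores. Il7r was -0.056 at Leiden 1.5, -0.012 without Scrublet doublets, -0.19 with the gate, -0.0028 without the heat-shock-led cluster, -0.019 without myeloid marker cells and -0.071 without high Scrublet scores. Il22 was -0.015 with the gate, Il17a -0.70 with 1000 variable genes and -0.26 with the stricter cell filter, and the low-count Csf2rb 1.75 with the gate and 0.0097 without high Scrublet scores. For other ILC3-like against NCR-like cells Cxxc1 was 0.025 with the gate and 0.13 without CD3 or Trac cells. Of the 8 lists called by camera, 0 were called with an estimated correlation and 3 by fry, and 15 of 96 list tests lost a call. Of 40 shares of classes, 24 moved. In replicate 1 LTi-like cells were 12.1% at Leiden 1.5, 24.9% with 1000 variable genes, 3.80% with the gate and 14.8% without high Scrublet scores, other ILC3-like cells 8.37% with 1000 variable genes, 31.1% with the gate and 18.3% without high Scrublet scores, and NCR-like cells 10.9% at Leiden 1.5, 4.23% with 1000 variable genes, 3.88% with the gate and 5.14% without high Scrublet scores. In replicate 2 LTi-like cells were 49.6% at Leiden 1.5, 49.6% with 1000 variable genes, 48.9% with the stricter filter, 48.2% without Scrublet doublets, 16.6% with the gate and 48.2% without high Scrublet scores. Other ILC3-like cells there were 16.8% at Leiden 0.6, 9.86% at Leiden 1.5, 12.2% with 1000 variable genes, 13.2% with the stricter filter and 45.7% with the gate, and NCR-like cells 5.31% at Leiden 1.5 and 2.95% with the gate. At Leiden 0.6 the ILC3-like cells of replicate 1 were not split, so the 3 comparisons and 2 shares were not run. Depth limits detection: thinned to 1500 molecules, cells of replicate 2 had Cxxc1 in 10.03% of LTi-like, 11.3% of other ILC3-like and 8.92% of NCR-like cells, Il22 in 71.7% and Il17a in 14.4% of LTi-like cells, and Csf2 in 16.2% of LTi-like and 23.2% of other ILC3-like cells. The gate rests on detection of single genes, so it depends on depth, and the cause of the other shifts was not tested. Leaving out a replicate leaves no test. It moved some changes by more than the standard deviation between the replicates. Without replicate 1 these were 14 named genes for NCR-like against LTi-like, 5 for other ILC3-like against LTi-like and 15 for other ILC3-like against NCR-like cells. Without replicate 2 they were 6, 2 and 4. Of 32 list medians with a replicate left out, 14 moved. A standard deviation of 2 values is wider than the distance of either from their mean. A change that did not move can therefore still have unequal replicates, as H2-Ab1 did for NCR-like against LTi-like cells (-4.19 and -1.35).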

Other observations

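The clusters described here were picked out, and their genes chosen, only after the result was seen, and none of the values below was tested. Leading genes are picked for a high ratio in their cluster, so no shares of them are given.

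T-cell-like cells contained populations found in both replicates. A cluster of 1113 and 876 cells was led in both by genes that include Il12rb2 and Tnfrsf4, and a cluster of 399 and 246 cells by genes that include Cd8a, Cd8b1, Ccl5 and Itgae. Foxp3, which regulatory T cells need, had a count in 2 of 2505 and 2 of 1308 T-cell-like cells. A cluster of 67 cells in replicate 1 was led by the interferon-stimulated genes Mx1 and Ifit1. ILC2-like cells, 60 and 75, were led in both by genes that include Il17rb and Calca, the gene for CGRP. They had Il5 in 6.67% and 17.3%, against 0.285% and 0 of 62 stromal or endothelial cells, and Cd3e in 23.3% and 52.0%, against 9.12% and 8.06%.

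LTi-like cells of replicate 2 were split into clusters led by different genes. The largest, of 916 cells, was led by genes that include the interferon-induced chemokine genes Cxcl9 and Cxcl10, and had Cd74 in 64.5% and Il22 in 89.1%. A cluster of 561 cells, with Cntn1 and Cxcr5, the receptor that guides cells to follicles, among its leading genes, had Cd4 in 50.8% and Il22 in 87.2%. A cluster of 77 cells, with Il17a and Il17f among its leading genes, had Il22 in 83.1%. The heat-shock-led cluster of 648 cells had Il22 in 43.7%. Stromal or endothelial cells of that replicate had Cd74 in 22.6%, Cd4 in 17.7% and Il22 in 30.6%.

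Cycling cells had a Cd3e count in 66.1% of 59 cells in replicate 1, at a median of 9050 reads, and in 10.7% of 122 cells in replicate 2, at a median of 4492.5 molecules, values in different units, of which that of replicate 2 is near the 8.06% of stromal or endothelial cells. Ccl22, a chemokine gene of migratory dendritic cells, led an unnamed cluster of 25 cells in replicate 1 and the 56 myeloid-like cells in replicate 2. Siglech, a marker of plasmacytoid dendritic cells, led an unnamed cluster of 45 cells in replicate 2.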
